A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

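Messenger RNA of 28 yeast samples was read on 2-colour Agilent arrays, 16 samples on the 8 arrays of design A and 12 on the 6 arrays of design B. Each sample was 1 channel, Cy3 or Cy5, of an array shared with a sample of another group, and every group held as many Cy3 as Cy5 samples. The groups were taken from the sample labels: 6 knockouts and wild type in 1 M sorbitol for 30 minutes in design A, and 4 labelled knockouts, wild type in sorbitol and wild type in synthetic complete medium in design B. No sample was moved between groups on account of its values.

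The values in all 3 deposited tables are log2: normalized log2 values per channel for each design, and log2 ratios to wild type that aggregate replicates. Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.3.1, subtracted background, and quantile-normalized in MATLAB with Bioinformatics Toolbox 3.4 (R2009b). For design A they first corrected for the place of each probe on the array with a Gaussian image filter. For design B they subtracted a Lowess fit of expression on the distance of the probe from the 3' UTR. The values of design A run from 5.23 to 17.23 and those of design B from -6.66 to 7.63, so the designs were analysed apart and no value of one was set against a value of the other.

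The tables hold 6218 genes in design A and 6221 in design B, 1 value per systematic name. Of all cells 13.4% and 13.8% are empty, and of those in genes with any value 98.2% and 98.7% fall on genes below the median signal, so dim genes were often not measured. An empty cell was treated as missing. Symbols came from the reference table of locus tags supplied with the data.

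Each design was fitted with limma 3.58.1 in R 4.3.3: group and dye as fixed terms, array as a random block whose correlation was estimated over all genes (0.847 in design A, 0.164 in design B), and moderated t statistics with default settings. With such a block the fitted log2 change leans on differences within arrays and can depart from the plain difference of group means, most of all in design A. A gene was tested where each group had at least 2 values. The p-values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05. Knockouts of design A were compared with its 4 wild-type samples and gal11 with pcl2. In design B each labelled knockout was compared with the samples labelled wild type in sorbitol, these with the samples labelled wild type in SC, and labelled knockouts with each other.

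30 gene lists written down before the data were examined were tested with cameraPR of limma on the moderated t statistics at a preset correlation of 0.01, for lists with at least 3 tested members. Their p-values were adjusted over all lists and comparisons of a design, and not every list is described or drawn. The list of ribosomal protein genes was drawn by symbol and also took in RPP1, a subunit of RNase P. The same test was run on the genes of each chromosome, which was chosen after the data were seen. The labelled sorbitol response was the 150 highest and 150 lowest genes between the groups labelled wild type in design B. It was tested as a list in design A, and in design B the share of it kept was read in samples other than those that ranked it.

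Named genes followed a rule written before the data were examined. In each comparison it took the deleted genes and up to 8 called genes in each direction with the largest change, if every sample of a group lay on 1 side of every sample of the other after removing the dye term. It also took up to 4 called members of each list described, by size of change, or up to 2 as values where none was called. The comparisons, tests, thresholds and most alternatives were also set before the data were examined.

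Alternatives were median centring, quantile normalization, no dye term, no array block, array as a fixed term, slide position as a covariate, replicate numbers as a block, dim genes left out, moderation with trend and robust settings, a 2-fold threshold, a fit of the compared groups alone without the array block, each sample left out, other list sizes, estimated correlation and fry for lists, and the deposited ratio table. Centring on genes measured in every sample, 1 value per group as the requirement, lists without the array block and chromosome IX left out were added after the data were seen. Testing each probe apart was not run, because the tables hold 1 value per gene. The Dixon test for a sample far from the rest was run on the 4 wild-type samples of design A, the only group with more than 2.

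The pipeline was tested on simulated data of the same layout, with a correlation of 0.5 between samples of an array in place of the estimated 0.847 and 0.164, so the shares below hold for that correlation alone. Of genes given a log2 change of 0.5, 1 and 2, in that order, 0%, 40.3% and 81.8% were called in the layout of asf1 against wild type, 4.48%, 38.8% and 89.4% in that of gal11 against pcl2 and 17.9%, 64.2% and 90.9% in that of hog1 against wild type. Unchanged genes made up 6.90%, 9.09% and 3.97% of the calls. Random numbers used the seed 1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.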

Results

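The series measured messenger RNA of budding yeast, Saccharomyces cerevisiae, on 2-colour Agilent microarrays. Strains lacking 1 or more genes and wild type were held for 30 minutes in 1 M sorbitol, a sugar alcohol that raises the osmolarity outside the cell. The 28 samples fall into 2 array designs. Design A held 16 samples: 2 each of the asf1, bem1, fus3, gal11, pcl2 and rvs167 knockouts and 4 of wild type, all in sorbitol. Design B held 12 samples: 2 each labelled hog1, tpk2, ssk2 ssk22 sho1 and ssk2 ssk22 ste11 in sorbitol, wild type in sorbitol, and wild type in synthetic complete medium (SC). Hog1 is the kinase that is switched on by high osmolarity. One branch upstream of it runs through the kinases Ssk2 and Ssk22 and the other through the membrane protein Sho1 and the kinase Ste11, so that each triple knockout is meant to lack both branches. Tpk2 is a catalytic subunit of protein kinase A.

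Each sample shared its array with a sample of another group. In design A the number of genes with a value ranged from 4779 in bem1 replicate 1 to 5593 in wild-type replicate 3, of 6218. In design B it ranged from 5150 in replicate 1 labelled tpk2 to 5580 in replicate 1 labelled wild type in SC, of 6221. The small number of arrays limits the precision. Of all list calls at a preset correlation, described below or not, 43 of 57 held with an estimated correlation in design A and 53 of 115 in design B. The p-values measure the spread between samples alone, because no label says whether the samples of a group came from separate cultures. Genes are given by symbol and systematic name, which holds the chromosome and arm. Changes are fitted log2 differences ± SE, with n = 2 per knockout, n = 4 for wild type in design A, and n = 2 for each group labelled wild type in design B.

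The deleted genes of design A were missing or lower where the labels said so. ASF1 (YJL115W), BEM1 (YBR200W), GAL11 (YOL051W) and PCL2 (YDL127W) had no value in either sample of their own knockout, and PCL2 had none in the bem1 knockout either. FUS3 (YBL016W) had no value in 1 sample of its knockout and a normalized log2 value of 6.94 in the other, against 10.89 to 10.97 in wild type. RVS167 (YDR388W) stood at 7.40 and 9.18 in its knockout against 13.68 to 13.99 in wild type, a fitted change of -5.26 ± 0.23 (adjusted p = 5.99e-08).

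Loss of Asf1, a chaperone of histones H3 and H4, went with more transcript of stress and storage-carbohydrate genes and less of ribosome biogenesis genes in sorbitol. Of the trehalose and glycogen genes, 11 of 21 measured members rose (adjusted over the list alone, 16 rose), with a median log2 change of 0.70 (camera adjusted p = 4.59e-10). GLC3 (YEL011W), the glycogen branching enzyme, rose by 1.29 ± 0.14 (adjusted p = 0.000339), GPH1 (YPR160W), glycogen phosphorylase, by 1.21 ± 0.17, and GSY1 (YFR015C), a glycogen synthase, by 1.25 ± 0.19. Among general stress genes driven by Msn2 and Msn4, 24 of 41 measured members rose (adjusted over the list alone, 27 rose), with a median of 0.58 (camera adjusted p = 6.66e-16) and HSP26 (YBR072W), a small heat-shock protein, at 1.41 ± 0.10. Hog1-dependent osmostress targets had a median of 0.64 (camera adjusted p = 1.59e-11), and 18 of 37 measured members rose (adjusted over the list alone, 22 rose). GRE1 (YPL223C), a hydrophilin, rose by 1.89 ± 0.19 and PUT4 (YOR348C), the proline permease, by 1.40 ± 0.16. Among the ribosome biogenesis genes, 27 of 84 measured members fell (adjusted over the list alone, 40 fell and 2 rose), for a median of -0.51 (camera adjusted p = 1.04e-18). UTP20 (YBL004W) and UTP10 (YJL109C), parts of the small-subunit processome, stood at -1.14 ± 0.28 and -1.02 ± 0.25. The histone genes had a median of 0.40 (camera adjusted p = 0.0233, and adjusted p = 0.0544 with an estimated correlation), where 4 of 11 measured members rose and 1 fell (adjusted over the list alone, 6 rose and 2 fell). HHT1 (YBR010W), a histone H3 gene, rose by 1.56 ± 0.23 and HTA1 (YDR225W), a histone H2A gene, by 1.40 ± 0.19. Among the meiosis and sporulation markers, 4 of 11 measured members rose and 1 fell (adjusted over the list alone, 6 rose and 1 fell), for a median of 0.44 (camera adjusted p = 0.015), or adjusted p = 0.226 with samples of an array treated as independent. Among the largest single changes, ADH2 (YMR303C), the alcohol dehydrogenase of ethanol use, rose by 1.96 ± 0.36 (adjusted p = 0.00602) and CIT2 (YCR005C), the peroxisomal citrate synthase, by 1.92 ± 0.23 (adjusted p = 0.000489). SNF11 (YDR073W), a subunit of the SWI/SNF chromatin remodeler, changed by -1.56 ± 0.17 (adjusted p = 0.00112). By limma, 645 of 5293 genes passed an adjusted p of 0.05, 491 higher and 154 lower, and 156 of them changed at least 2-fold. This count moved with the settings of the fit. With samples of an array treated as independent, 11 genes passed, and 5 of the 16 genes named by size kept their call, with every sign kept. Within arrays alone 0 passed by limma (974 at an unadjusted p under 0.05). Replicate numbers as a block also left 0 by limma (568 at an unadjusted p under 0.05). The count was 246 without asf1 replicate 1, 114 without asf1 replicate 2, 416 without wild-type replicate 2 and 142 without wild-type replicate 4.

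Bem1 is a scaffold protein of cell polarity that also serves pheromone signalling. Most genes were lower in its knockout, with a median log2 change over all genes of -0.30, and changes below are given relative to that median, while calls and counts rest on the fitted changes themselves. Mating and filamentous growth genes were lower still. For the pheromone response genes the median was -0.56 relative to all genes (camera adjusted p = 0.00373), and 14 of 20 measured members fell and 1 rose (adjusted over the list alone, 16 fell and 1 rose). KAR4 (YCL055W), a regulator of mating genes, stood at -1.77 ± 0.14 (adjusted p = 2.03e-06) and BAR1 (YIL015W), the protease that degrades alpha factor, at -1.31 ± 0.30. Of the filamentous growth targets, 8 of 9 measured members fell (adjusted over the list alone, 8 fell), with a median of -0.49 relative to all genes (camera adjusted p = 0.0356), or adjusted p = 0.109 with samples of an array treated as independent. TEC1 (YBR083W), a transcription factor of that programme, stood at -1.21 ± 0.10 and MEP2 (YNL142W), an ammonium permease, at -0.60 ± 0.13. G2/M genes had a median of -0.46 relative to all genes (camera adjusted p = 0.0358, and adjusted p = 0.403 with an estimated correlation), and 12 of 18 measured members fell and 1 rose (adjusted over the list alone, 12 fell and 1 rose). CLB2 (YPR119W), a mitotic cyclin, stood at -1.32 ± 0.11 and CDC5 (YMR001C), the polo kinase, at -1.27 ± 0.13. General stress genes stood above the other genes: 11 of 41 measured members rose and 9 fell (adjusted over the list alone, 11 rose and 9 fell), with a median of 0.42 relative to all genes (camera adjusted p = 0.00148). SOD2 (YHR008C), mitochondrial superoxide dismutase, stood at 1.87 ± 0.12, whereas YGP1 (YNL160W), a secreted glycoprotein, stood at -1.35 ± 0.18. Within the meiosis and sporulation markers, 2 of 5 measured members rose (adjusted over the list alone, 2 rose), with a median of 0.77 relative to all genes (camera adjusted p = 0.0293), or adjusted p = 0.0857 with samples of an array treated as independent. Among the largest single changes were PRM7 (YDL039C), a pheromone-regulated gene, at -3.36 ± 0.20 (adjusted p = 7.38e-07), TRA1 (YHR099W), a subunit of the SAGA and NuA4 complexes, at -2.97 ± 0.14 (adjusted p = 1.73e-07), and JSN1 (YJR091C), a Puf-family RNA-binding protein, at -2.70 ± 0.11. On the other side, TRP2 (YER090W), a subunit of anthranilate synthase, stood at 3.03 ± 0.33 (adjusted p = 6.96e-05) and ISW1 (YBR245C), a chromatin remodeler, at 2.69 ± 0.29. In limma, 2396 of 4705 genes passed an adjusted p of 0.05, 530 higher and 1866 lower, and 783 of them changed at least 2-fold. With samples centred on the genes measured in every sample, the split was 848 higher and 1239 lower and the median of all genes -0.07. The count was 855 with samples of an array treated as independent, 1596 without bem1 replicate 2 and 1515 without wild-type replicate 1.

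Fus3 is the mitogen-activated kinase of the pheromone response. Its knockout had more transcript of cell wall genes and less of sulfur, amino acid and protein folding genes than wild type in sorbitol. Among the cell wall integrity targets, 6 of 25 measured members rose (adjusted over the list alone, 6 rose), for a median of 0.13 (camera adjusted p = 0.00104). PRM5 (YIL117C) rose by 1.65 ± 0.20 (adjusted p = 0.00101), KTR2 (YKR061W), a mannosyltransferase, by 0.91 ± 0.10 and PST1 (YDR055W), a wall protein, by 0.76 ± 0.11. Of the sulfur and methionine genes, 5 of 23 measured members fell (adjusted over the list alone, 8 fell and 1 rose), with a median of -0.42 (camera adjusted p = 0.000854, and adjusted p = 0.0986 with an estimated correlation), and MET6 (YER091C), methionine synthase, stood at -1.11 ± 0.17. Among the Gcn4 targets of amino acid synthesis, 10 of 48 measured members fell and 1 rose (adjusted over the list alone, 10 fell and 1 rose), for a median of -0.20 (camera adjusted p = 0.0113), or adjusted p = 0.191 with samples of an array treated as independent. ARG1 (YOL058W), argininosuccinate synthetase, changed by -1.14 ± 0.11. Within the heat-shock and folding genes, 5 of 28 measured members fell and 1 rose (adjusted over the list alone, 12 fell and 1 rose), with a median of -0.45 (camera adjusted p = 0.00521), or adjusted p = 0.226 with such samples independent. SSC1 (YJR045C) and KAR2 (YJL034W), the Hsp70 proteins of mitochondria and of the endoplasmic reticulum, stood at -0.89 ± 0.10 and -0.87 ± 0.14, whereas HSP26 rose by 1.58 ± 0.10 (adjusted p = 2.87e-05). Single genes with large changes were CDC8 (YJR057W), thymidylate kinase, at 3.35 ± 0.28 (adjusted p = 0.000115), HSP30 (YCR021C), a plasma membrane stress protein, at 2.48 ± 0.24 (adjusted p = 0.00025), HUG1 (YML058W-A), a gene of the DNA damage checkpoint, at 2.16 ± 0.17, PHO84 (YML123C), the phosphate transporter, at -1.54 ± 0.33, and NCE103 (YNL036W), carbonic anhydrase, at -1.52 ± 0.13 (adjusted p = 0.000115). With limma, 355 of 5048 genes passed an adjusted p of 0.05, 120 higher and 235 lower, and 68 of them changed at least 2-fold. Treating samples of an array as independent left 5 genes, and reading within arrays alone left 0 by limma (732 at an unadjusted p under 0.05), with 2 of the 16 genes named by size still called in the former. The count was 83 without fus3 replicate 1, 85 without fus3 replicate 2, 50 without wild-type replicate 2 and 208 without wild-type replicate 4.

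Gal11 is a subunit of the Mediator tail, through which activators reach RNA polymerase II. Its knockout had less transcript of ribosome biogenesis and proteasome genes and more of sulfur and glycogen genes. The ribosome biogenesis genes had a median of -0.82 (camera adjusted p = 1.37e-13), where 33 of 84 measured members fell (adjusted over the list alone, 42 fell). TSR1 (YDL060W), a maturation factor of the small subunit, changed by -2.57 ± 0.21 (adjusted p = 4.28e-05) and ENP1 (YBR247C), a processing factor of the same subunit, by -2.56 ± 0.44. Of the proteasome genes, 11 of 33 measured members fell (adjusted over the list alone, 18 fell), with a median of -0.89 (camera adjusted p = 1.81e-06), and RPN6 (YDL097C), a lid subunit, stood at -1.36 ± 0.24. Sulfur and methionine genes had a median of 0.88 (camera adjusted p = 0.000129, and adjusted p = 0.0741 with an estimated correlation), and 11 of 28 measured members rose and 1 fell (adjusted over the list alone, 16 rose and 2 fell). MMP1 (YLL061W), the permease of S-methylmethionine, rose by 3.66 ± 0.25 (adjusted p = 9.46e-05) and SUL2 (YLR092W), a sulfate permease, by 2.06 ± 0.26. Within the trehalose and glycogen genes, 5 of 21 measured members rose (adjusted over the list alone, 8 rose and 1 fell), with a median of 0.63 (camera adjusted p = 0.0209), led by GSY1 at 4.26 ± 0.36 (adjusted p = 5.39e-05) and GLC3 at 2.46 ± 0.27. The meiosis and sporulation markers had a median of 0.98 (camera adjusted p = 0.00893), where 5 of 14 measured members rose (adjusted over the list alone, 6 rose). Among the largest single changes were ADH2 at 4.92 ± 0.70 (adjusted p = 0.00102), NRG1 (YDR043C), a repressor of glucose-repressed genes, at 3.27 ± 0.23, HXT4 (YHR092C), a hexose transporter, at 3.24 ± 0.50, TPO2 (YGR138C), a polyamine exporter, at -4.99 ± 0.35 (adjusted p = 2.48e-05), ADE17 (YMR120C), an enzyme of purine synthesis, at -3.09 ± 0.22, and HPT1 (YDR399W), the hypoxanthine phosphoribosyltransferase, at -2.84 ± 0.28. Under limma, 920 of 5342 genes passed an adjusted p of 0.05, 564 higher and 356 lower, and 677 of them changed at least 2-fold. No gal11 sample shared an array or a slide row with wild type, and the median SE was 0.34. The count was 419 with replicate numbers as a block and 612 without gal11 replicate 2.

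Pcl2 is a cyclin of the Pho85 kinase that acts in G1. Its knockout differed from wild type in 3 of 5203 genes by limma, all lower, with 521 genes at an unadjusted p under 0.05. With slide position as a covariate, or with replicate numbers as a block, 0 genes passed by limma (468 at an unadjusted p under 0.05 in each). No pcl2 sample shared an array or a slide row with wild type, and the median SE was 0.34, against 0.17 in bem1 and 0.18 in rvs167, which did share arrays. The 3 genes were YGR035C, a gene of unknown function, at -2.29 ± 0.21 (adjusted p = 0.0115), NCE103 at -1.76 ± 0.25 (adjusted p = 0.0392) and HSV2 (YGR223C), a phosphoinositide-binding protein of autophagy, at -1.42 ± 0.20 (adjusted p = 0.0392). With samples of an array treated as independent, 2 of the 3 kept their call by limma and NCE103 did not (adjusted p = 0.171). A few lists shifted as sets. For the sulfur and methionine genes, 0 of 24 measured members passed by limma, over all genes or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05. Their median log2 change was -0.44 (camera adjusted p = 0.00201, and adjusted p = 0.141 with an estimated correlation). The filamentous growth targets had a median of -0.54 (camera adjusted p = 0.00441); 0 of 11 measured members passed by limma, over all genes or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05. The Hog1-dependent osmostress targets had a median of 0.26 (camera adjusted p = 0.0107); 0 of 35 measured members passed by limma, over all genes or adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. The count of changed genes was 2 without pcl2 replicate 1. It was 0 by limma without pcl2 replicate 2 or without any of wild-type replicates 1, 2, 3 and 4, where 527, 403, 537, 505 and 502 genes had an unadjusted p under 0.05.

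Rvs167 is an amphiphysin that shapes membranes in endocytosis. Its knockout had more transcript of heat-shock and general stress genes and less of ribosome biogenesis, iron uptake and proteasome genes. Within the heat-shock and folding genes, 15 of 28 measured members rose and 3 fell (adjusted over the list alone, 16 rose and 3 fell), with a median of 0.64 (camera adjusted p = 3.22e-05). BTN2 (YGR142W), which sorts misfolded proteins, rose by 4.79 ± 0.16 (adjusted p = 9.5e-09), HSP26 by 3.61 ± 0.10 (adjusted p = 5.03e-09) and CUR1 (YPR158W), a relative of BTN2, by 2.10 ± 0.22. Within the general stress genes, 22 of 41 measured members rose and 2 fell (adjusted over the list alone, 22 rose and 2 fell), with a median of 0.39 (camera adjusted p = 2.5e-05), HSP30 at 4.75 ± 0.24 (adjusted p = 1.66e-07) and HSP78 (YDR258C), a mitochondrial chaperone, at 1.65 ± 0.17. Among the Hog1-dependent osmostress targets, 17 of 37 measured members rose and 2 fell (adjusted over the list alone, 17 rose and 2 fell), for a median of 0.37 (camera adjusted p = 0.00255). TPO4 (YOR273C), a polyamine exporter, rose by 3.20 ± 0.15, whereas AQR1 (YNL065W), a transporter of the plasma membrane, changed by -2.43 ± 0.10. Within the ribosome biogenesis genes, 64 of 84 measured members fell and 1 rose (adjusted over the list alone, 66 fell and 1 rose), with a median of -1.24 (camera adjusted p = 1.19e-32). NOG1 (YPL093W) and NOG2 (YNR053C), GTPases of large-subunit assembly, changed by -3.00 ± 0.11 (adjusted p = 2.58e-08) and -2.83 ± 0.11. Of the iron regulon, 11 of 26 measured members fell and 4 rose (adjusted over the list alone, 12 fell and 5 rose), with a median of -0.43 (camera adjusted p = 0.00373). Wild-type replicate 3, the array mate of rvs167 replicate 2, stood high in the mean of this list, and without it the median was -0.33 (camera adjusted p = 0.00443). SIT1 (YEL065W) and ARN1 (YHL040C), siderophore transporters, stood at -3.34 ± 0.20 (adjusted p = 5.0e-07) and -2.80 ± 0.14 and FIT1 (YDR534C), a wall mannoprotein that holds siderophores, at 2.81 ± 0.18. Proteasome genes had a median of -0.41 (camera adjusted p = 0.0068), and 15 of 33 measured members fell and 1 rose (adjusted over the list alone, 16 fell and 1 rose). The member that rose was RPN4 (YDL020C), the transcription factor of proteasome genes, at 2.28 ± 0.23. Within the meiosis and sporulation markers, 11 of 15 measured members rose and 1 fell (adjusted over the list alone, 11 rose and 1 fell), with a median of 1.22 (camera adjusted p = 0.00148). TPO2 at -5.74 ± 0.18 (adjusted p = 9.5e-09), PRM7 at -3.64 ± 0.20 and HPT1 at -3.35 ± 0.15 were among the largest decreases, and ZPS1 (YOL154W), a zinc-regulated surface protein, was among the largest increases at 4.36 ± 0.21. By limma, 1943 of 5383 genes passed an adjusted p of 0.05, 1174 higher and 769 lower, and 678 of them changed at least 2-fold. With samples of an array treated as independent the count was 551, and within arrays alone, with array as a fixed term, it was 965. It was 321 with replicate numbers as a block, 245 with the compared groups alone and no array block, 1229 without rvs167 replicate 2 and 1254 without wild-type replicate 3.

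The gal11 and pcl2 knockouts shared both their arrays with dyes exchanged, so their difference was read without a wild-type sample. Ribosome biogenesis, proteasome and osmostress transcripts were lower in gal11 than in pcl2 and sulfur genes higher. For the ribosome biogenesis genes the median was -0.95 (camera adjusted p = 1.98e-15), and 56 of 84 measured members fell and 2 rose (adjusted over the list alone, 60 fell and 2 rose). Among the proteasome genes, 26 of 33 measured members fell and 1 rose (adjusted over the list alone, 26 fell and 1 rose), for a median of -0.76 (camera adjusted p = 2.15e-05). Sulfur and methionine genes went the other way, where 18 of 25 measured members rose and 1 fell (adjusted over the list alone, 19 rose and 2 fell), with a median of 1.34 (camera adjusted p = 1.6e-06). SUL2 was higher by 2.83 ± 0.12 (adjusted p = 4.58e-08) and MET3 (YJR010W), ATP sulfurylase, by 1.93 ± 0.13. The Hog1-dependent osmostress targets had a median of -0.56 (camera adjusted p = 0.017), where 17 of 35 measured members fell and 5 rose (adjusted over the list alone, 17 fell and 5 rose). GPP1 (YIL053W), a glycerol phosphatase, and HSP12 (YFL014W), a membrane-binding stress protein, were lower at -2.43 ± 0.36 and -2.39 ± 0.32. For the meiosis and sporulation markers the median was 0.95 (camera adjusted p = 0.0113), and 7 of 9 measured members rose and 1 fell (adjusted over the list alone, 7 rose and 1 fell). ADH2 differed by 4.93 ± 0.33 (adjusted p = 7.48e-07), JEN1 (YKL217W), the lactate permease, by 3.87 ± 0.17, TPO2 by -5.16 ± 0.17 (adjusted p = 6.15e-09) and ADE17 by -3.37 ± 0.10. In limma, 2616 of 5175 genes passed an adjusted p of 0.05, 1493 higher and 1123 lower, and 835 of them changed at least 2-fold. The count was 1134 with no dye term and 510 with samples of an array treated as independent.

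**Figure D1:**
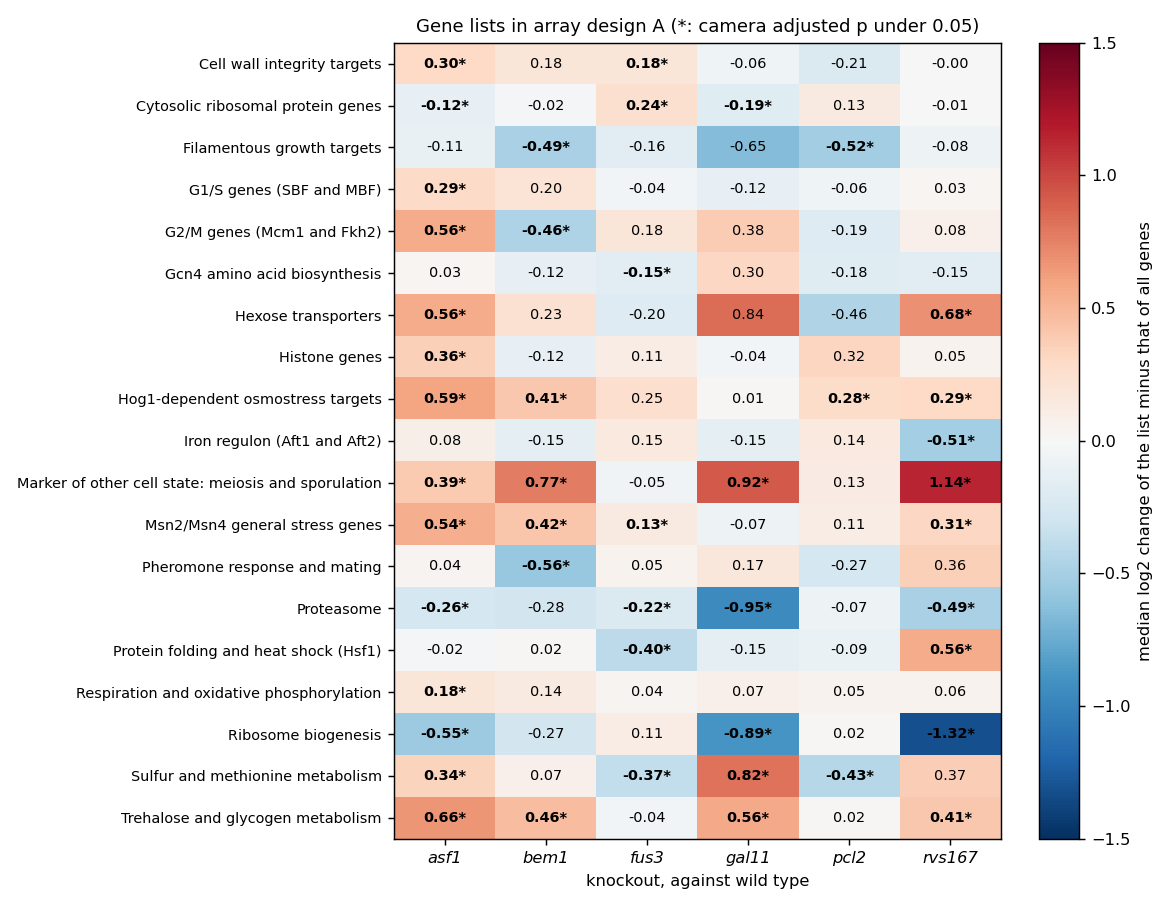
Heat map of the median log2 change of gene lists that passed in at least 1 knockout, minus that of all genes, for the 6 knockouts of design A against wild type in sorbitol. Bold values with an asterisk had a camera adjusted p under 0.05. Ribosome biogenesis genes had the lowest value of that list in the rvs167 knockout, -1.32.

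Of the deleted genes of design B, TPK2 (YPL203W) was lowest under its label but kept a value there. SSK2 (YNR031C) and HOG1 (YLR113W) did not follow their labels. SHO1 (YER118C), STE11 (YLR362W) and SSK22 (YCR073C) lacked values in some of the samples labelled wild type. Each group below is therefore named by its label, and directions between groups hold for the labels alone. SSK2 had no value in any of the 4 samples labelled wild type and stood between 0.38 and 0.77 in the 4 samples labelled as lacking it. SHO1 had no value under the label wild type in sorbitol, and -0.88 and -0.92 under ssk2 ssk22 sho1. Under wild type in SC it was higher, at -0.29 and -0.44. STE11 stood at -1.16 and -0.66 under ssk2 ssk22 ste11 and higher, at 0.47 and -0.17, under wild type in sorbitol. Under wild type in SC it had 1 value, -2.16. SSK22 had no value under wild type in SC, -0.49 and -0.67 under wild type in sorbitol, and -3.34 to -1.97 in samples labelled as lacking it. It stood at -1.54 and -1.68 under hog1 and at -2.31 and -1.64 under tpk2. HOG1 was present under the hog1 label, at 1.02 and 1.05 against 1.80 and 0.93 under wild type in sorbitol. TPK2 stood at -0.73 and -0.56 in the samples labelled tpk2, the percentiles 35.7 and 38.8 of their values. It stood at -0.03 and -0.17 under hog1 and at 1.03 and 0.73 under wild type in sorbitol. Against the latter the fitted change was -1.52 ± 0.12 (limma adjusted p = 1.4e-05), which does not by itself show a loss. LEU2 (YCL018W) and MET17 (YLR303W), genes of leucine and methionine synthesis whose loss is a common strain marker, were singled out after their values were seen. LEU2 stood at 2.08 and 1.80 under wild type in sorbitol, at -2.88 and -3.54 under hog1, and at -5.42 and -5.47 under ssk2 ssk22 sho1. MET17 stood between 2.16 and 2.94 in the samples labelled wild type and had no value in 3 of the 4 labelled as triple knockouts. Groups of design B thus differ in marker transcripts too. Differences between labels can hold effects of strain background, which was not tested apart.

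**Figure D2:**
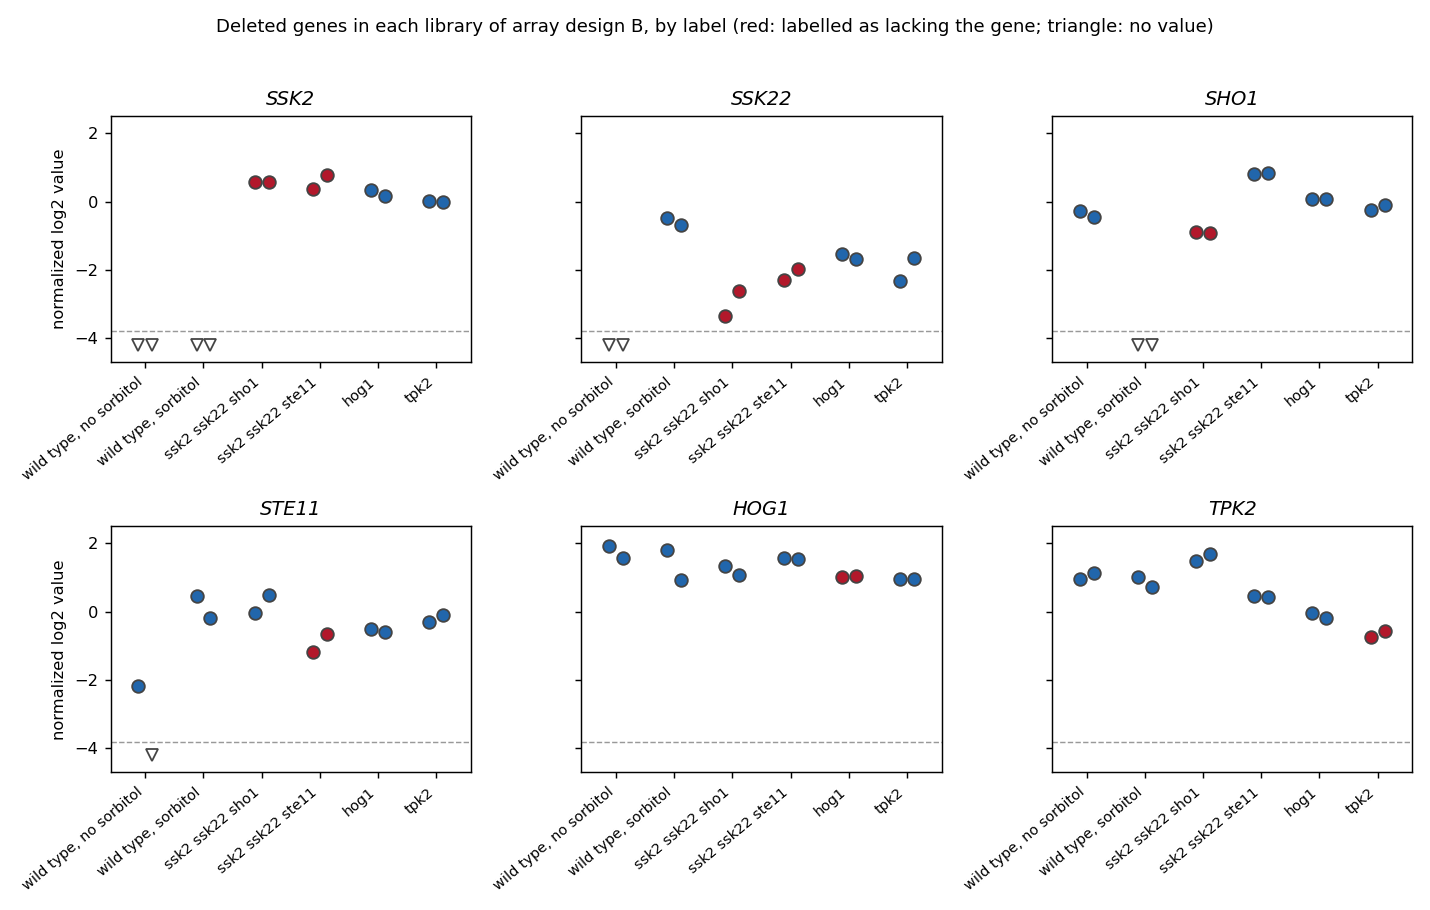
Normalized log2 value of SSK2, SSK22, SHO1, STE11, HOG1 and TPK2 in each of the 12 samples of design B, by label. Red points are samples labelled as lacking the gene and open triangles samples with no value. SSK2 has no value in the 4 samples labelled wild type.

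By its labels, wild type in sorbitol against wild type in SC reads the response to sorbitol. SSK2 had no value in any of these samples. STE11 was missing or low, at -2.16, under the SC label, against 0.47 and -0.17 under the sorbitol label. The differences below, those of mating genes included, are therefore a sorbitol response only if the labels hold. Mating, stress and glycerol genes were higher under the sorbitol label and ribosome genes lower. Of the pheromone response genes, 19 of 29 measured members rose and 1 fell (adjusted over the list alone, 19 rose and 2 fell), with a median log2 change of 1.28 (camera adjusted p = 1.6e-17). BAR1 differed by 4.57 ± 0.24 (adjusted p = 0.000271), FUS1 (YCL027W), a cell fusion protein, by 3.52 ± 0.37 and MFA1 (YDR461W), an a-factor gene, by 3.43 ± 0.13. Among the glycerol genes, 5 of 14 measured members rose (adjusted over the list alone, 5 rose), for a median of 0.29 (camera adjusted p = 0.000229). GPD1 (YDL022W), glycerol-3-phosphate dehydrogenase, differed by 0.76 ± 0.17, and GPP1 and GPP2 (YER062C), the glycerol phosphatases, by 1.71 ± 0.21 and 1.26 ± 0.14. Within the Hog1-dependent osmostress targets, 16 of 35 measured members rose and 3 fell (adjusted over the list alone, 17 rose and 3 fell), with a median of 0.54 (camera adjusted p = 3.33e-05, and adjusted p = 0.258 with an estimated correlation). CTT1 (YGR088W), cytosolic catalase, differed by 1.61 ± 0.19 and HSP12 by 2.33 ± 0.23. The general stress genes had a median of 0.51 (camera adjusted p = 5.35e-06, and adjusted p = 0.244 with an estimated correlation), where 20 of 41 measured members rose and 1 fell (adjusted over the list alone, 20 rose and 1 fell). Among the ribosome biogenesis genes, 56 of 84 measured members fell and 1 rose (adjusted over the list alone, 61 fell and 2 rose), for a median of -0.55 (camera adjusted p = 7.18e-09), and KRR1 (YCL059C), a processing factor of the small subunit, changed by -1.62 ± 0.08. GIS3 (YLR094C), of unknown function, at 5.20 ± 0.26 (adjusted p = 6.36e-05) and ATP6 (Q0085), a mitochondrially encoded subunit of ATP synthase, at -5.23 ± 0.31 (adjusted p = 9.25e-05) changed most in each direction. Genes of chromosome IX, BAR1 and GPP1 among them, stood apart from the rest: the median of its 189 genes was 0.93, and 182 of them lay above the median of all genes (camera adjusted p = 1.04e-64). With limma, 1872 of 5250 genes passed an adjusted p of 0.05, 690 higher and 1182 lower, and 353 of them changed at least 2-fold. The split was 846 higher and 956 lower with samples centred on the genes measured in every sample. The count was 1012 without SC replicate 1, 932 without SC replicate 2 and 1105 without sorbitol replicate 6, and 1042 with no dye term.

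The samples labelled hog1 had far less transcript of stress and folding genes than those labelled wild type in sorbitol, and more of ribosome biogenesis and respiration genes. For the Hog1-dependent osmostress targets the median was -2.80 (camera adjusted p = 6.1e-12), and 24 of 30 measured members fell and 2 rose (adjusted over the list alone, 24 fell and 2 rose). PUT4 was lower at -7.07 ± 0.39 (adjusted p = 3.41e-06), HXT5 (YHR096C), a hexose transporter, at -6.60 ± 0.60 and HSP12 at -5.84 ± 0.23. Within the general stress genes, 32 of 39 measured members fell and 5 rose (adjusted over the list alone, 32 fell and 5 rose), with a median of -2.19 (camera adjusted p = 6.87e-15). SSA4 (YER103W), an inducible Hsp70, stood at -7.01 ± 0.28 (adjusted p = 1.35e-06) and HSP42 (YDR171W), a small heat-shock protein, at -5.82 ± 0.26. Of the heat-shock and folding genes, 21 of 25 measured members fell and 1 rose (adjusted over the list alone, 21 fell and 1 rose), with a median of -1.74 (camera adjusted p = 4.89e-11), and BTN2 stood at -6.81 ± 0.34. Within the glycerol genes, 7 of 14 measured members fell and 3 rose (adjusted over the list alone, 7 fell and 3 rose), with a median of -0.54 (camera adjusted p = 0.0366, and adjusted p = 0.0948 with an estimated correlation), or adjusted p = 0.0778 with chromosome IX left out. GPD1 stood at -3.17 ± 0.17 and GPP2 at -3.40 ± 0.14. Within the ribosome biogenesis genes, 81 of 84 measured members rose and 1 fell (adjusted over the list alone, 81 rose and 1 fell), with a median of 1.61 (camera adjusted p = 4.93e-22), and NOC2 (YOR206W) differed by 2.74 ± 0.28. Of the respiration genes, 40 of 46 measured members rose and 1 fell (adjusted over the list alone, 42 rose and 1 fell), with a median of 1.48 (camera adjusted p = 4.08e-13), and ATP3 (YBR039W), a subunit of ATP synthase, differed by 2.24 ± 0.11. CTR1 (YPR124W), the copper transporter, was higher by 5.86 ± 0.12 (adjusted p = 1.42e-07) and PHO84 by 4.59 ± 0.27. HOG1 itself had a fitted value of -0.33 ± 0.23 (adjusted p = 0.242). The median of chromosome IX was -1.03. Under limma, 3547 of 5064 genes passed an adjusted p of 0.05, 1914 higher and 1633 lower, and 1585 of them changed at least 2-fold.

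Against the same samples labelled wild type in sorbitol, those labelled ssk2 ssk22 sho1 had more transcript of osmostress genes. Of the Hog1-dependent osmostress targets, 25 of 35 measured members rose and 4 fell (adjusted over the list alone, 25 rose and 4 fell), with a median of 1.73 (camera adjusted p = 1.4e-12). GRE1 was higher by 5.60 ± 0.38 (adjusted p = 0.000124), TKL2 (YBR117C), a transketolase, by 5.54 ± 0.38 and ALD3 (YMR169C), an aldehyde dehydrogenase, by 4.74 ± 0.42. Of the glycerol genes, 9 of 14 measured members rose and 2 fell (adjusted over the list alone, 9 rose and 2 fell), with a median of 0.62 (camera adjusted p = 0.0132), DAK1 (YML070W), dihydroxyacetone kinase, at 3.04 ± 0.18 and GPD1 at 1.39 ± 0.17. Ergosterol genes had a median of -1.06 (camera adjusted p = 7.8e-10), and 23 of 28 measured members fell and 2 rose (adjusted over the list alone, 23 fell and 2 rose). ERG3 (YLR056W) and ERG5 (YMR015C), sterol desaturases, stood at -3.17 ± 0.13 (adjusted p = 4.6e-06) and -2.70 ± 0.15. Within the G1/S genes, 26 of 35 measured members fell and 3 rose (adjusted over the list alone, 28 fell and 3 rose), with a median of -0.78 (camera adjusted p = 2.15e-07), PCL1 (YNL289W), a G1 cyclin, at -2.46 ± 0.19 and MCD1 (YDL003W), a cohesin subunit, at -2.31 ± 0.11. LEU2 and URA3 (YEL021W), the latter of uracil synthesis, had the lowest values, -7.39 ± 0.16 (adjusted p = 3.32e-06) and -5.80 ± 0.54, and SSK22 stood at -2.40 ± 0.17. SHO1 and SSK2 had no value in the samples labelled wild type, so no change was fitted for them. The median of chromosome IX was -0.94. By limma, 3111 of 5198 genes passed an adjusted p of 0.05, 1661 higher and 1450 lower, and 973 of them changed at least 2-fold.

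The samples labelled ssk2 ssk22 ste11 had more transcript of ribosome biogenesis and phosphate genes and less of respiration genes than those labelled wild type in sorbitol. Of the ribosome biogenesis genes, 78 of 84 measured members rose and 2 fell (adjusted over the list alone, 78 rose and 2 fell), with a median of 1.39 (camera adjusted p = 4.98e-19), and TSR1 was higher by 2.70 ± 0.17 (adjusted p = 5.98e-06). The respiration genes had a median of -0.63 (camera adjusted p = 2.87e-06), where 33 of 46 measured members fell and 4 rose (adjusted over the list alone, 33 fell and 4 rose). CYT1 (YOR065W), cytochrome c1, stood at -2.56 ± 0.13 and QCR9 (YGR183C), also of complex III, at -2.51 ± 0.10. Among the phosphate regulon, 12 of 16 measured members rose and 2 fell (adjusted over the list alone, 12 rose and 2 fell), for a median of 1.39 (camera adjusted p = 0.00112, and adjusted p = 0.126 with an estimated correlation), PHO84 at 6.95 ± 0.25 (adjusted p = 9.86e-07) and PHO5 (YBR093C), the acid phosphatase, at 2.72 ± 0.25. Within the Hog1-dependent osmostress targets, 18 of 35 measured members fell and 9 rose (adjusted over the list alone, 18 fell and 9 rose), with a median of -0.48 (camera adjusted p = 0.0339, and adjusted p = 0.589 with an estimated correlation), PUT4 at -5.51 ± 0.36 and HXT5 at -4.07 ± 0.55. Of the meiosis and sporulation markers, 6 of 6 measured members fell (adjusted over the list alone, 6 fell), with a median of -2.04 (camera adjusted p = 0.000548, with no correlation that could be estimated), or adjusted p = 0.055 with chromosome IX left out. Among the deleted genes, STE11 stood at -1.06 ± 0.15 (limma adjusted p = 0.000528) and SSK22 at -1.55 ± 0.15, but neither change by itself shows a loss. The SSK22 values of -2.28 and -1.97 overlapped those under the tpk2 label, -2.31 and -1.64. The STE11 values of -1.16 and -0.66 lay a little below those under the hog1 label, -0.50 and -0.59. The median of chromosome IX was -1.03. In limma, 3666 of 5119 genes passed an adjusted p of 0.05, 1878 higher and 1788 lower, and 1486 of them changed at least 2-fold.

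In the samples labelled tpk2, genes of amino acid synthesis and ribosome biogenesis were higher and stress and mating genes lower than in those labelled wild type in sorbitol. Of the Gcn4 targets of amino acid synthesis, 47 of 51 measured members rose and 2 fell (adjusted over the list alone, 48 rose and 2 fell), with a median of 2.10 (camera adjusted p = 6.42e-21). HIS4 (YCL030C), of histidine synthesis, was higher by 3.85 ± 0.14 (adjusted p = 8.46e-07) and BAT1 (YHR208W), a branched-chain aminotransferase, by 3.60 ± 0.12. Among the ribosome biogenesis genes, 80 of 84 measured members rose and 1 fell (adjusted over the list alone, 80 rose and 1 fell), for a median of 1.55 (camera adjusted p = 1.01e-20) and UTP10 at 3.05 ± 0.28. For the general stress genes the median was -2.32 (camera adjusted p = 3.01e-21), and 39 of 40 measured members fell and 1 rose (adjusted over the list alone, 39 fell and 1 rose). SSA4 stood at -7.47 ± 0.28 (adjusted p = 8.75e-07) and HSP26 at -7.18 ± 0.20 (adjusted p = 5.69e-07). Of the pheromone response genes, 14 of 18 measured members fell and 1 rose (adjusted over the list alone, 14 fell and 1 rose), with a median of -2.27 (camera adjusted p = 2.33e-05); another 8 of the 31 on the arrays had no value under the tpk2 label. GPA1 (YHR005C), the alpha subunit of the pheromone G protein, stood at -6.22 ± 0.35 (adjusted p = 3.44e-06) and STE2 (YFL026W), the alpha factor receptor, at -4.87 ± 0.27. Among the meiosis and sporulation markers, 3 of 4 measured members fell (adjusted over the list alone, 3 fell), for a median of -2.31 (camera adjusted p = 0.0218, with no correlation that could be estimated), or adjusted p = 0.471 with chromosome IX left out. Auxotrophic strain markers had a median of 1.34 (camera adjusted p = 0.00252, and adjusted p = 0.258 with an estimated correlation), and 7 of 9 measured members rose and 1 fell (adjusted over the list alone, 7 rose and 1 fell). MAL31 (YBR298C) and MAL11 (YGR289C), maltose permeases, had the highest values, 8.08 ± 0.39 (adjusted p = 1.7e-06) and 7.15 ± 0.41. The median of chromosome IX was -0.94 and that of chromosome III -0.47 (adjusted p = 0.052). With limma, 3610 of 5044 genes passed an adjusted p of 0.05, 1761 higher and 1849 lower, and 1673 of them changed at least 2-fold.

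**Figure D3:**
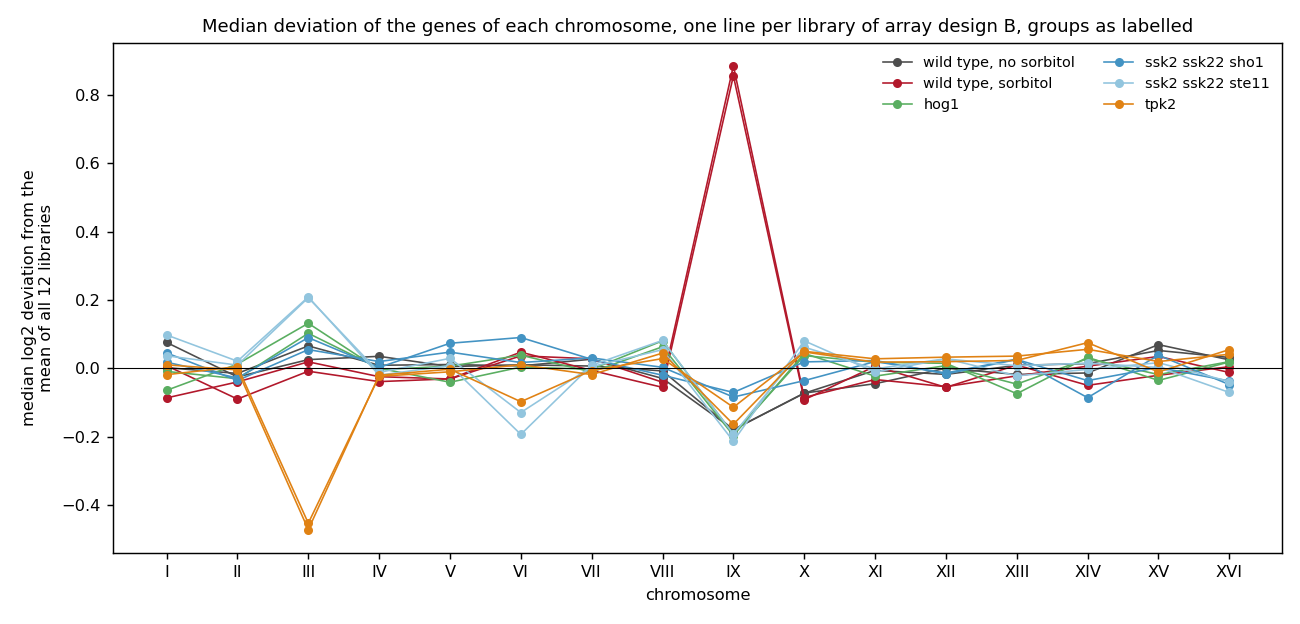
Median log2 deviation of each chromosome's genes from the mean of the 12 samples of design B, with chromosomes along the horizontal axis and 1 line per sample. Chromosome IX stands above the other chromosomes in both samples labelled wild type in sorbitol, and its median change against those labelled wild type in SC was 0.93.

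The remaining comparisons of design B set labelled knockouts against each other, without a sample labelled wild type. Between the labels hog1 and ssk2 ssk22 sho1, osmostress genes were lower in hog1 and ribosome biogenesis genes higher. Of the Hog1-dependent osmostress targets, 30 of 31 measured members fell and 1 rose (adjusted over the list alone, 30 fell and 1 rose), with a median of -4.07 (camera adjusted p = 3.74e-31), ALD3 at -8.57 ± 0.41 (adjusted p = 1.58e-06) and SIP18 (YMR175W), a hydrophilin, at -7.56 ± 0.46. Among the glycerol genes, 10 of 15 measured members fell and 2 rose (adjusted over the list alone, 10 fell and 2 rose), for a median of -1.04 (camera adjusted p = 1.9e-05), STL1 (YDR536W), the glycerol symporter, at -6.85 ± 0.67 (adjusted p = 0.000602) and GPD1 at -4.56 ± 0.17. Of the general stress genes, 36 of 40 measured members fell and 3 rose (adjusted over the list alone, 36 fell and 3 rose), with a median of -2.77 (camera adjusted p = 2.95e-31) and CTT1 at -7.31 ± 0.19. The proteasome genes had a median of -0.95 (camera adjusted p = 8.51e-08), where 33 of 33 measured members fell (adjusted over the list alone, 33 fell). Of the ribosome biogenesis genes, 84 of 84 measured members rose (adjusted over the list alone, 84 rose), with a median of 1.95 (camera adjusted p = 1.24e-38). CTR1 differed by 6.00 ± 0.13 (adjusted p = 2.71e-07) and CYC1 (YJR048W), cytochrome c, by 5.39 ± 0.53. SHO1 was higher under the hog1 label by 0.98 ± 0.09 and SSK22 by 1.37 ± 0.17. Under limma, 3363 of 5110 genes passed an adjusted p of 0.05, 1673 higher and 1690 lower, and 1425 of them changed at least 2-fold.

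Between the labels hog1 and ssk2 ssk22 ste11, respiration genes were higher in hog1. Of these, 45 of 46 measured members rose and 1 fell (adjusted over the list alone, 45 rose and 1 fell), with a median of 2.28 (camera adjusted p = 7.48e-75), SDH1 (YKL148C) and SDH2 (YLL041C), subunits of succinate dehydrogenase, at 3.43 ± 0.09 (adjusted p = 7.42e-07) and 3.13 ± 0.09. Among the Hog1-dependent osmostress targets, 26 of 30 measured members fell and 3 rose (adjusted over the list alone, 26 fell and 3 rose), for a median of -1.61 (camera adjusted p = 1.47e-13), AQR1 at -5.58 ± 0.40 and HSP12 at -4.60 ± 0.23. Within the phosphate regulon, 11 of 14 measured members fell (adjusted over the list alone, 11 fell), with a median of -1.15 (camera adjusted p = 1.2e-08), PHO3 (YBR092C), an acid phosphatase, at -3.59 ± 0.11 and PHO5 at -2.94 ± 0.28. Within the cell wall integrity targets, 16 of 24 measured members fell and 1 rose (adjusted over the list alone, 16 fell and 1 rose), with a median of -0.58 (camera adjusted p = 2.85e-05) and CWP1 (YKL096W), a wall mannoprotein, at -3.72 ± 0.36. HXT3 (YDR345C), a hexose transporter, was lowest at -6.13 ± 0.20 (adjusted p = 9.21e-07) and ARO10 (YDR380W), a decarboxylase of aromatic amino acid breakdown, highest at 5.51 ± 0.19 (adjusted p = 1.14e-06). By limma, 2334 of 5087 genes passed an adjusted p of 0.05, 1172 higher and 1162 lower, and 617 of them changed at least 2-fold. The count was 1542 without hog1 replicate 2 and 1520 without ssk2 ssk22 ste11 replicate 1.

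The 2 triple knockouts differ by label in SHO1 and STE11. Osmostress and glycerol genes were lower under the ste11 label than under the sho1 label and ribosome genes higher. Within the Hog1-dependent osmostress targets, 31 of 35 measured members fell (adjusted over the list alone, 32 fell), with a median of -2.10 (camera adjusted p = 1.37e-22), GRE1 at -6.07 ± 0.38 (adjusted p = 8.06e-05) and PUT4 at -5.38 ± 0.39. Within the glycerol genes, 9 of 14 measured members fell (adjusted over the list alone, 9 fell), with a median of -0.94 (camera adjusted p = 3.89e-05), GPD1 at -3.60 ± 0.17 and GPP2 at -3.14 ± 0.14. Of the trehalose and glycogen genes, 18 of 22 measured members fell (adjusted over the list alone, 18 fell), with a median of -1.38 (camera adjusted p = 1.28e-11) and TPS2 (YDR074W), trehalose phosphatase, at -2.90 ± 0.13. Within the ribosome biogenesis genes, 83 of 84 measured members rose (adjusted over the list alone, 83 rose), with a median of 1.84 (camera adjusted p = 2.04e-52), and of the ribosomal protein genes 54 of 55 measured members rose (adjusted over the list alone, 54 rose), with a median of 0.97 (camera adjusted p = 1.17e-15). Within the meiosis and sporulation markers, 4 of 6 measured members fell and 1 rose (adjusted over the list alone, 5 fell and 1 rose), with a median of -1.46 (camera adjusted p = 0.0331, with no correlation that could be estimated), or adjusted p = 0.233 with chromosome IX left out. HO (YDL227C), the mating-type endonuclease, had the highest value, 5.56 ± 0.14 (adjusted p = 6.7e-06). SHO1 differed by 1.72 ± 0.09 (adjusted p = 1.75e-05) and STE11 by -1.15 ± 0.16. In limma, 2968 of 5181 genes passed an adjusted p of 0.05, 1320 higher and 1648 lower, and 977 of them changed at least 2-fold.

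The samples labelled hog1 and tpk2 shared both their arrays with dyes exchanged. Amino acid, sulfur and hexose transport genes were lower in hog1 and respiration genes higher. Of the Gcn4 targets, 50 of 52 measured members fell (adjusted over the list alone, 52 fell), with a median of -1.44 (camera adjusted p = 6.24e-40), SNZ1 (YMR096W) and SNO1 (YMR095C), of vitamin B6 synthesis, at -5.17 ± 0.16 (adjusted p = 1.24e-06) and -5.80 ± 0.11. Among the sulfur and methionine genes, 19 of 28 measured members fell and 2 rose (adjusted over the list alone, 19 fell and 3 rose), for a median of -1.10 (camera adjusted p = 3.7e-12) and SUL1 (YBR294W), a sulfate permease, at -5.41 ± 0.62. Among the hexose transporters, 6 of 8 measured members fell and 1 rose (adjusted over the list alone, 6 fell and 1 rose), for a median of -3.15 (camera adjusted p = 3.71e-10), HXT3 at -6.70 ± 0.18 (adjusted p = 1.21e-06) and HXT2 (YMR011W) at -4.74 ± 0.14. Among the respiration genes, 43 of 46 measured members rose (adjusted over the list alone, 43 rose), for a median of 0.94 (camera adjusted p = 2.32e-15) and MDH1 (YKL085W), mitochondrial malate dehydrogenase, at 2.11 ± 0.10. Within the auxotrophic strain markers, 7 of 8 measured members fell and 1 rose (adjusted over the list alone, 7 fell and 1 rose), with a median of -1.18 (camera adjusted p = 1.01e-08) and LEU2 at -6.49 ± 0.15 (adjusted p = 1.24e-06). TPK2 was higher under the hog1 label by 0.54 ± 0.11, and genes of chromosome III had a median of 0.62 (adjusted p = 2.61e-06). With limma, 2441 of 5072 genes passed an adjusted p of 0.05, 1475 higher and 966 lower, and 636 of them changed at least 2-fold. With no dye term the count was 1228.

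**Figure D4:**
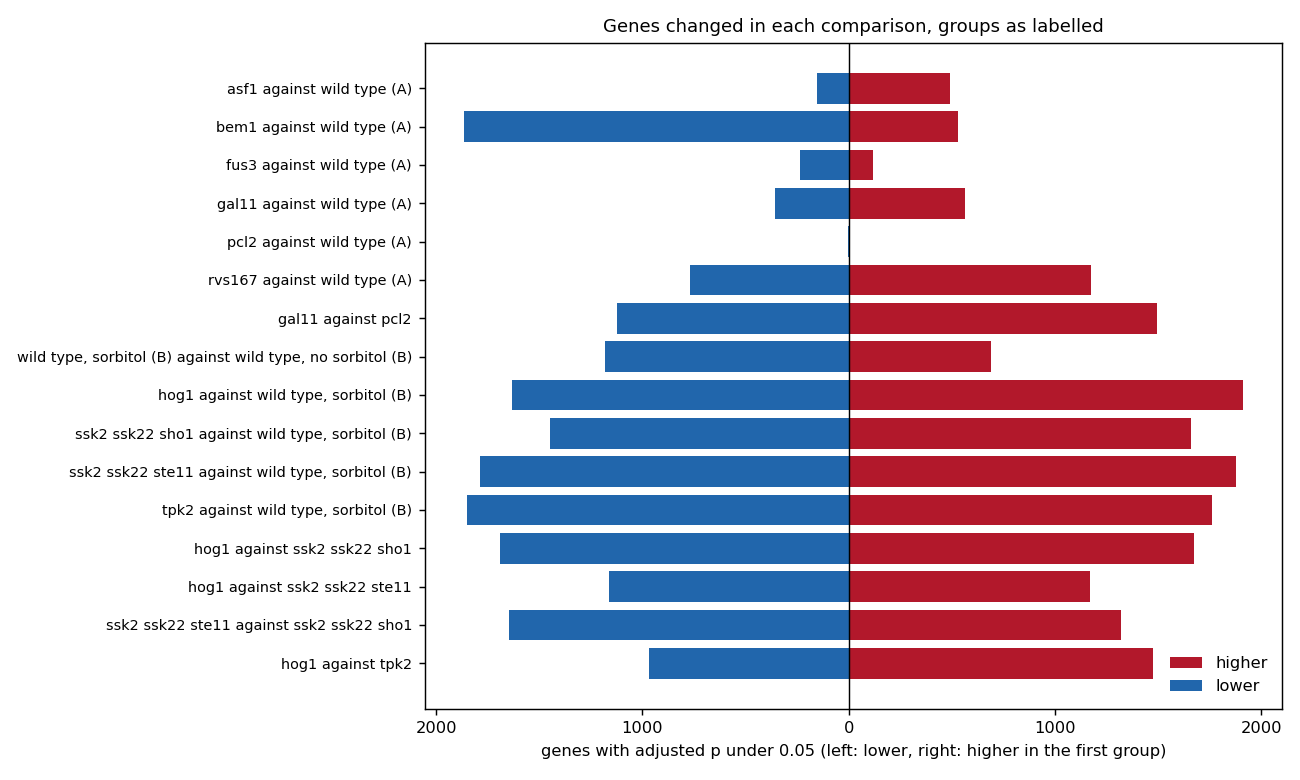
Number of genes changed in each of the 16 comparisons, as horizontal bars (limma, adjusted p under 0.05), with genes higher in the first group to the right and genes lower to the left. Groups are named by label. The bars run from 3 genes for pcl2 against wild type to 3666 for ssk2 ssk22 ste11 against wild type in sorbitol.

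How much of the labelled sorbitol response each labelled knockout kept was read with the 150 genes highest and the 150 lowest between the groups labelled wild type, ranked on samples of 1 dye and read in samples of the other (mean ± SD of 2 readings, no test). The 4 samples that define this response had no value for SSK2, so the shares are of a difference between labels, which is a sorbitol response only if the labels hold. No share was computed with the labels exchanged, because samples are grouped by label alone, and no order of the knockouts is read from these shares. For the higher genes the share was -1.76% ± 6.50 under the hog1 label, 40.4% ± 13.05 under ssk2 ssk22 sho1, 9.80% ± 5.44 under ssk2 ssk22 ste11 and -0.48% ± 0.54 under tpk2. For the lower genes it was 20.9% ± 4.06, 56.3% ± 5.46, 31.1% ± 3.47 and 14.8% ± 3.65. The fitted list of 150 higher genes held 72 of chromosome IX and that of 150 lower genes held 1. With chromosome IX left out, that share of the higher genes was -24.6% under hog1, 67.3% under ssk2 ssk22 sho1 and -13.8% under tpk2. The same fitted lists were tested in the knockouts of design A, which share no sample with them. In the asf1 knockout all genes had a median of 0.043, and 491 of 5293 rose and 154 fell. There the higher genes of the list had a median of 0.11 (camera adjusted p = 0.00651), where 26 of 132 rose, and the lower genes one of 0.16 (camera adjusted p = 0.031). Without asf1 replicate 2 both calls ended, at medians of 0.04 and 0.01, and the call of the lower genes also ended without wild-type replicate 2, at 0.18, and without wild-type replicate 4, at 0.12. In the rvs167 knockout the higher genes had a median of 0.20 (camera adjusted p = 0.00651), where 45 of 133 rose and 13 fell. In the fus3 knockout the lower genes had a median of 0.09 (camera adjusted p = 0.00175). The higher genes did not pass in bem1, at -0.35 (camera adjusted p = 0.572) where all genes stood at -0.30, or in gal11, at 0.11 (camera adjusted p = 0.285), although those outside chromosome IX passed in gal11 at 0.26.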

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

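All tests of the labels and of chromosome IX in this part were chosen after the results were seen, as was the test of weak arrays, whereas the test of normalization for bem1 was chosen before.

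A sample far from the others of its group was looked for with the Dixon ratio in the 4 wild-type samples of design A, over 54 measures. The ratio passed its critical value in 4 of them, where chance alone would bring it there in about 1 of 20. ASF1 in replicate 2 stood at 9.27 against 9.61 to 9.66 in the others, a ratio of 0.868. BEM1 in replicate 4 stood at 7.64 against 8.99 to 9.09, a ratio of 0.933. The mean of the glycerol genes in replicate 4 stood at 11.94 against 11.75 to 11.77, a ratio of 0.892. The mean of the iron regulon in replicate 3 stood at 10.23 against 10.04 to 10.07, a ratio of 0.851.

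In design B the genes SSK2, SHO1 and STE11 had values in samples labelled as lacking them. SSK2 was missing in all 4 samples labelled wild type. SHO1 was missing under wild type in sorbitol, and STE11 was missing or low, at -2.16, under wild type in SC. In the other wild-type group SHO1 and STE11 had values. Both the labels and the row exchange described below would give this, so it does not favour the labels. SHO1 at -0.29 and -0.44 under SC, and STE11 at 0.47 and -0.17 under sorbitol, lay above the samples labelled as lacking them. Probes outside the deleted part of each gene, or signal from related sequences, are argued against by SSK2, which had no value in 4 of the 4 samples labelled wild type. An exchange of the arrays of rows 1 and 2 of the slide between data and labels could account for these 3 genes. It was tested in columns 1 and 2 alone and was among 2 of 24 assignments that put all 3 in place. The labels as given put 0 of the 3 in place. Both assignments with all 3 in place take the samples labelled wild type as the triple knockouts. They differ only in which pair labelled as a triple knockout would be wild type in SC. The exchange also accounts for lower osmostress genes under the ste11 label than under the sho1 label (median -2.10). It accounts as well for LEU2, which the strain named in the file header lacks. The highest LEU2 value under the triple labels minus its lowest under the wild-type labels was -4.42. The same gap was -6.53 for MET17, with 1 value under the triple labels, and -5.05 for URA3. All 3 of these genes had values in the 4 samples labelled wild type in design B and none in the 16 samples of design A. For SSK22 the values part. The samples labelled wild type in SC, which under the exchange would lack it, were the only ones of design B with no value, against their label. Those labelled wild type in sorbitol, which under the exchange would also lack it, stood at least 1.45 above the median of the others. This argues against the exchange for the latter. SSK22 was thus out of place both as labelled and with the rows exchanged. The arrays labelled hog1 and tpk2, in columns 3 and 4 of row 1, have no array of row 2 in this series to exchange with, so the HOG1 signal under the hog1 label stays open, no biological explanation was tested, and every comparison was kept as labelled, although under the exchange the labelled sorbitol response would be a difference between triple knockouts.

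Genes of chromosome IX were 1.04 higher, relative to all genes, under the label wild type in sorbitol than under wild type in SC. An artefact of the 2 arrays they were hybridised to is argued against by their array mates, whose highest median deviation on chromosome IX was -0.19. The authors' normalization of these columns is argued against by the other nuclear chromosomes, whose largest shift was 0.079. An extra copy of chromosome IX in these cells could account for the shift and remains a hypothesis, since the right arm differed from the left by -0.039. DNA was not measured in this series.

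Most genes were lower in the bem1 knockout, whose samples also held the lowest numbers of values, ranks 1 and 3 of 16. Normalization of columns that hold different numbers of values could account for most of it: the shift predicted from the numbers of values was -0.20 of -0.29 observed, or 70.3%, over 4581 genes measured in every sample. Weak arrays could not be judged from the array mates of the bem1 samples, because these parted. By number of values the mate of bem1 replicate 1 ranked 14 of 16, above the median, and that of bem1 replicate 2 ranked 7, below it. A broad fall in transcription in the knockout stays open and was not tested.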

How the results depend on the processing

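Alternatives that leave out chromosome IX, centre on genes measured in every sample, ask for 1 value per group or drop the array block from the list tests were chosen after the data were seen. Named genes mostly kept their call under another normalization: of 1708 results for named genes, median centring ended 3 calls, quantile normalization 19 and centring on complete genes 31. More calls ended with no dye term (285), no array block (319) or a fit of the compared groups alone that also dropped the array block (500), and with array as a fixed term 205 of 730 ended. Replicate numbers as a block ended 296 of 1117. Against the ratios deposited by the authors, 193 of 1027 values moved, and over all genes the fitted changes correlated with those ratios at 0.74 in asf1 and 0.72 in fus3. In design B the deposited ratios equalled the fitted changes (correlation 1, median absolute difference 5e-07). Its values among the 1027 could therefore not move, and the pooled share understates the movement in design A. The 2-fold bar lowers a count by its construction; for every other setting below the cause was not tested. Where 1 sample of a group was left, it was assumed to vary like the other groups. Dim genes were measured in fewer samples, which limits what can be said of them.

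With no dye term the count of changed genes was 48 in asf1, 1203 in bem1, 22 in fus3, 774 in rvs167, 1134 between gal11 and pcl2, 1228 between the labels hog1 and tpk2, and 1042 between the groups labelled wild type. With samples of an array treated as independent it was 11 in asf1, 855 in bem1, 5 in fus3, 551 in rvs167 and 510 between gal11 and pcl2. With array as a fixed term it was 965 in rvs167, and by limma 0 in asf1 and 0 in fus3, where 974 and 732 genes had an unadjusted p under 0.05. With slide position as a covariate it was 0 by limma in pcl2 (468 at an unadjusted p under 0.05).

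Replicate numbers as a block gave 1184 genes in bem1, 23 in fus3, 419 in gal11 and 321 in rvs167, and by limma 0 in asf1 and 0 in pcl2 (568 and 468 at an unadjusted p under 0.05). Samples of the same replicate number did not move together in most pairs of groups (median r 0.03 in design A and 0.04 in design B). In some they did: r passed 0.1 in 8 of 21 pairs of design A (highest 0.72) and 4 of 10 of design B (highest 0.37). This block was not run where the group labelled wild type in sorbitol in design B took part, since its numbers 5 and 6 are shared with no other group. Fitting the compared groups alone and dropping the array block, both at once, gave 998 genes between the groups labelled wild type, 267 in bem1 and 245 in rvs167. The same pair of changes gave 0 by limma in asf1, fus3, pcl2 and between gal11 and pcl2, with 543, 526, 968 and 1061 genes at an unadjusted p under 0.05.

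Counts of at least 2-fold change were 156 in asf1, 783 in bem1, 68 in fus3, 678 in rvs167, 835 between gal11 and pcl2, and 353 between the groups labelled wild type. Under the labels against wild type in sorbitol they were 1585 for hog1, 973 for ssk2 ssk22 sho1, 1486 for ssk2 ssk22 ste11 and 1673 for tpk2. Between labels they were 1425 for hog1 and ssk2 ssk22 sho1, 617 for hog1 and ssk2 ssk22 ste11, 977 for the triple knockouts and 636 for hog1 and tpk2.

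Leaving out each sample in turn gave counts of 114 to 840 in asf1, 1515 to 2464 in bem1, 50 to 460 in fus3, 612 to 815 in gal11, 0 to 2 in pcl2, 1229 to 1993 in rvs167, 932 to 1897 between the groups labelled wild type, and 1520 to 1764 between the labels hog1 and ssk2 ssk22 ste11. The 0 in pcl2 by limma came without pcl2 replicate 2, with 527 genes at an unadjusted p under 0.05, and without each wild-type sample.

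For gene lists, fry called 121 of 208 in design A and 209 of 260 in design B, against 57 and 115 by camera. The tests differ in question, since fry asks whether a list changed at all and camera whether it changed more than other genes. An estimated correlation left 53 in design B. Without wild-type replicate 4, which stood high in the mean of the glycerol genes, that list began to pass in asf1, at a median of 0.31 (camera adjusted p = 0.0287, and 0.112 with it); this was chosen after the data were seen. The labelled sorbitol response had these medians in design A. With 50 genes per direction the calls of the higher genes in asf1 (0.079) and the lower genes in fus3 (0.091) ended. With 300 genes the call of the lower genes in asf1 ended (0.070) and that in rvs167 began (-0.035). Restricted to Hog1-dependent osmostress targets, the higher genes in pcl2 turned from -0.07 to 0.37. Without chromosome IX the call of the higher genes in gal11 began (0.26). Leaving out samples gave medians of 0.042 to 0.21 for the higher and 0.014 to 0.23 for the lower genes in asf1.

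The share of the labelled response, in %, moved as follows, always with the groups as labelled. With 50 genes it was 27.6 of the higher genes under ssk2 ssk22 ste11 and 3.43 under tpk2, and of the lower genes 28.3 under hog1, 50.3 under ssk2 ssk22 sho1, 46.2 under ssk2 ssk22 ste11 and 3.89 under tpk2. With 300 genes it was -3.93 of the higher genes under tpk2, and of the lower 6.68, 62.2, 10.1 and 6.84 in the same order of labels. Ranked and read in the same samples it was 18.6 and 3.32 of the higher genes under ssk2 ssk22 ste11 and tpk2, and 49.3, 22.2 and 10.67 of the lower under ssk2 ssk22 sho1, ssk2 ssk22 ste11 and tpk2. Without chromosome IX it was -24.6 of the higher genes under hog1, 67.3 under ssk2 ssk22 sho1 and -13.8 under tpk2.

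A few single genes changed sign, and the cause was not tested. These were MET2 in asf1 without asf1 replicate 2 (-0.073, and 1.41 without replicate 1), GDH1 in bem1 without wild-type replicate 1 (-0.19, and 2.87 without bem1 replicate 1), RAS1 in bem1 without bem1 replicate 2 (0.055, and -1.24 without replicate 1), TIS11 in bem1 with replicate numbers as a block (-0.30), HHF1 in rvs167 in the deposited ratio table (-0.0093), and SUN4 in rvs167 with replicate numbers as a block (0.013) and in the deposited ratio table (0.43).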

Other observations

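The values in this part were all chosen after they were seen.

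PRM7, a gene regulated by pheromone, was low in 3 knockouts of design A that differ in function: -3.36 ± 0.20 relative to the median of all genes in bem1, -3.92 ± 0.38 in gal11 and -3.64 ± 0.20 in rvs167, each against the same 4 wild-type samples. TPO2 and HPT1 were likewise low in both gal11, at -4.99 ± 0.35 and -2.84 ± 0.28, and rvs167, at -5.74 ± 0.18 and -3.35 ± 0.15. Between gal11 and pcl2, which uses no wild-type sample, PRM7 stood at -2.92 ± 0.18, TPO2 at -5.16 ± 0.17 and HPT1 at -2.95 ± 0.13.

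Genes encoded in the mitochondrion had a median log2 change of 0.71 over 11 genes in gal11 (camera adjusted p = 0.99) and 0.55 in rvs167 (adjusted p = 0.99). Against samples labelled wild type in sorbitol their median was -1.21 over 17 genes under the label ssk2 ssk22 sho1 (adjusted p = 0.0486) and -0.91 under ssk2 ssk22 ste11 (adjusted p = 0.732). The ste11 label against the sho1 label gave 0.22 (adjusted p = 0.998), so no difference between these labels was called. Genes of chromosome III were higher under the hog1 label than under the tpk2 label, with 90 of 130 called higher and 9 lower.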
